A study of Mus musculus with 8 samples.

How the data were processed

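RNA was measured in 8 mouse HSPC libraries, 4 groups of 2. Per the labels' protocols, total RNA was purified with an RNeasy Plus Micro kit and libraries were made with the NEB Ultra II Directional kit. Per the submitters' processing notes, the tools used were Trim Galore 0.6.6, STAR 2.7.6a and featureCounts (version not given in the sources used here), with GRCm38 (mm10); the notes give no order, and the strand setting and annotation are not given in the sources used here. The authors deposited 1 table of raw, unnormalised read counts per gene with a gene length, and no replicate was pooled. All 8 columns of counts were used.

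Groups came from the sample titles, since the source and cell type labels call every library dKO, the wild-type ones included. The table lists 24421 genes by symbol. Of these, 23159 symbols matched the reference table of GRCm38.p6, and 99.4% of the matched genes overlapped its position. There was no mitochondrially encoded row, so that list was not tested. Without the strand setting, overlapping and antisense genes cannot be separated, and genes with near-identical copies, such as histones and the Ly6 and Ifi families, are uncertain where reads were shared.

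Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 12744 genes, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion was fitted to all 8 libraries with group as the only term, leaving 4 residual degrees of freedom. Library totals were 15531344 to 22329749 counts and the common biological coefficient of variation was 0.0637. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Standard errors were obtained from the fold change and its F statistic. CPM values use the TMM-scaled library sizes. A fold against a group at 0 counts was set against a floor of 3 counts in a library, which covers counting error only.

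Before the data were examined, 5 comparisons, 30 gene lists, the rule for named genes and the alternatives were fixed. The rule named Prmt1, Ctnnb1 and Hoxa9, then the 6 largest increases and 6 largest decreases among called genes at a mean of 5 CPM or more with non-overlapping libraries and an established symbol, and up to 4 called members of each list with the smallest p, some of which are left out for room. Of the 30 lists 29 were tested, with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. The comparison of dKO_MUT with WT_EV, the autosomal counts and the counts of list members without single libraries were added after the data were seen.

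The steps were tested on simulated data for dKO_PRMT1 vs dKO_EV over 12744 genes: 41.7% of genes changed 1.25-fold were recovered, 69.4% at 1.5-fold, 86.0% at 2-fold and 91.8% at 4-fold. Of 178 genes called there, 10 were unchanged, and with no change simulated in dKO_EV vs WT_EV 0 genes were called by edgeR. The interferon list, lowered as a set in dKO_PRMT1, was called lower. Camera also called 1 other list there, though no other list was changed as a set, and 0 lists in dKO_EV vs WT_EV. Replicates differed by more than sampling noise in each group, with a chi-square per degree of freedom of 3.65 to 6.43, so none was counted as a duplicate. The highest value was that of dKO_EV. Alternatives were DESeq2 size factors, other count filters, DESeq2 1.42.0, limma voom, a fit of the compared groups alone, a replicate block, a threshold of 0.01 and each library left out. Relations between comparisons with shared dKO_EV libraries were set beside 20 simulations of unchanged groups.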

Results

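Haematopoietic stem and progenitor cells (HSPCs), the blood-forming cells of the marrow, were profiled by RNA sequencing after retrieval from mice that had received a primary transplant. The series title names the genes lost in the double knockout (dKO) as beta-catenin (Ctnnb1), the transcriptional effector of canonical Wnt signalling, and Hoxa9, a homeobox transcription factor of stem and progenitor cells. The insert tested was PRMT1, the main enzyme of asymmetric arginine dimethylation. There were 8 libraries in 4 groups of 2: wild-type cells with an empty vector (WT_EV), dKO cells with an empty vector (dKO_EV), dKO cells with an enzymatically dead PRMT1 mutant (dKO_MUT) and dKO cells with wild-type PRMT1 (dKO_PRMT1). The library totals ran from 15531344 counts in dKO_EV replicate 1 to 22329749 in dKO_EV replicate 2. Of the 24421 listed genes, 12744 were tested. Effects are log2 fold changes ± standard error between groups of n = 2 libraries. The words "rose" and "fell" are used for genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread was pooled over the 4 groups and, for each gene, drawn towards that of other genes. The median prior degrees of freedom were 30.4, against 4 residual.

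The targeted and transduced genes were examined first, in every library. Prmt1 (chromosome 7, 44976755 to 44986420, GRCm38) stood at 188 and 192 CPM (counts scaled to library size) in WT_EV and at 190 and 194 CPM in dKO_EV. It reached 1744 and 1758 CPM in dKO_MUT and 981 and 976 CPM in dKO_PRMT1. The species and codon usage of the inserts are not given in the sources used here, so how much of their transcript was counted at mouse Prmt1 is unknown. Against dKO_EV it rose by 3.19 ± 0.04 with the mutant and by 2.35 ± 0.04 with wild-type PRMT1. It was lower in dKO_PRMT1 than in dKO_MUT, at -0.84 ± 0.03 (adjusted p = 2.6e-19). The genotype label of dKO_MUT replicate 2 names PRMT2 where its title groups it with the PRMT1 mutant. Prmt2 (chromosome 10, 76207226 to 76237865) had 74 and 73 counts in the dKO_MUT replicates, against 89 and 138 in dKO_EV, and Prmt1 was at the same level in both dKO_MUT libraries.

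Hoxa9 (chromosome 6, 52223097 to 52227370) fell from 18.2 and 17.2 CPM in WT_EV to 5.79 and 3.63 CPM in dKO_EV, a change of -1.93 ± 0.32 (adjusted p = 9.4e-05). Its levels in dKO_MUT were 4.85 and 1.95 CPM and in dKO_PRMT1 3.76 and 1.87 CPM. Against dKO_EV the changes of -0.43 ± 0.35 with the mutant and -0.72 ± 0.35 with wild-type PRMT1 did not pass the threshold, although the first was -1.24 and past it without dKO_MUT replicate 1 (adjusted p = 0.0427) and 0.07 without dKO_MUT replicate 2. The second was -1.30 without dKO_PRMT1 replicate 1 (adjusted p = 0.0532) and -0.30 without replicate 2 (0.751), past the threshold in neither. Ctnnb1 (chromosome 9, 120933400 to 120960507) fell less, from 444 and 455 CPM to 391 and 379 CPM, at -0.23 ± 0.04 (adjusted p = 6.5e-05). The sources used here do not give the deleted exons, so the count over the whole gene does not check the deletion.

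**Figure D1:**
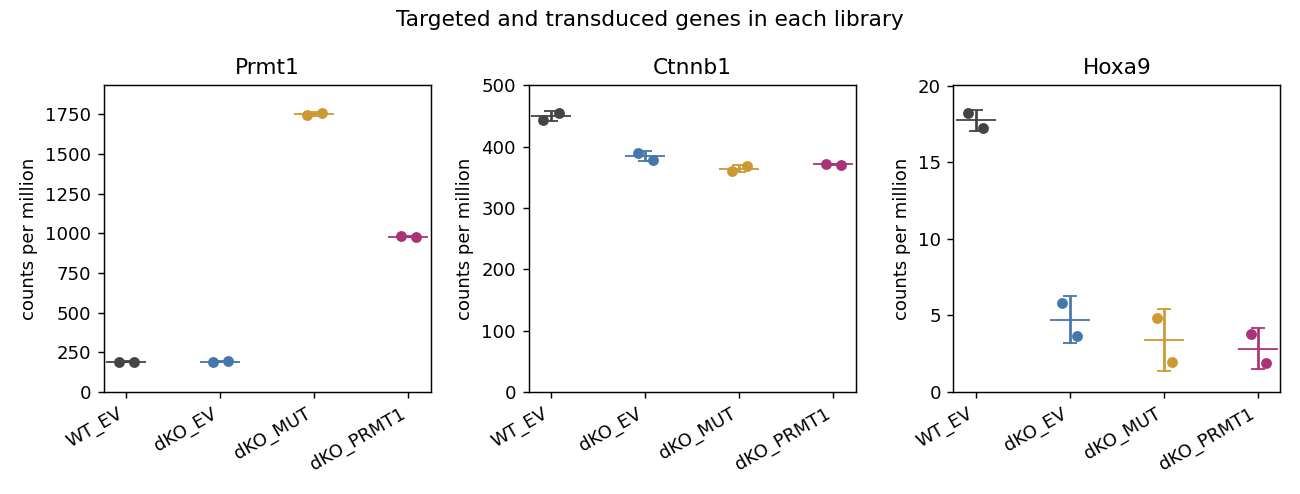
Prmt1, Ctnnb1 and Hoxa9 in CPM in each library of the 4 groups. Points are the 2 libraries of a group, the horizontal mark is their mean and the error bar their SD; Prmt1 was near 190.1 in WT_EV and 192 in dKO_EV, 1751 in dKO_MUT and 978 in dKO_PRMT1.

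The comparison of dKO_EV with WT_EV asks how the loss of both genes changed the cells. Neutrophil and granule markers rose in the dKO cells for 21 of the 29 tested members and fell for 2, among them Itgb2l. Among those that rose were Chil3 (1.23 ± 0.03), Cd177 (1.36 ± 0.04), the iron-binding granule protein Ltf (0.98 ± 0.03) and the antimicrobial peptide Camp (1.07 ± 0.04). Glycolysis genes fell, with 16 of 24 lower and 3 higher. Among those lower were phosphoglycerate kinase Pgk1 (-0.89 ± 0.04), lactate dehydrogenase Ldha (-0.79 ± 0.03) and triosephosphate isomerase Tpi1 (-0.83 ± 0.04). Of the 18 mast cell, basophil and eosinophil markers 9 fell and 1 rose, led by Prss34 (-1.55 ± 0.07), Cpa3 (-1.01 ± 0.05) and Mcpt8 (-0.98 ± 0.05). Ribosome biogenesis and MYC targets fell for 15 of 38 members, including the nucleolar proteins Ncl (-0.28 ± 0.03) and Npm1 (-0.28 ± 0.03). These 4 lists were called by camera, and their calls held with an estimated correlation between genes (adjusted p = 0.0085, 0.012, 0.0094 and 0.019). Adjusted over the list alone, the counts were 21 higher and 3 lower for neutrophils, 4 and 16 for glycolysis, 1 and 10 for mast cells, and 0 and 22 for ribosome biogenesis. Without WT_EV replicate 1, 9 ribosome biogenesis members fell, and without dKO_MUT replicate 2, 2 mast cell list members rose.

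The DNA replication list, which the series title makes of interest, fell in 10 of 58 members and rose in 1, with a median of -0.09. The helicase subunits Mcm3 (-0.23 ± 0.04) and Mcm7 (-0.19 ± 0.04) and the initiation factors Orc5 (-0.57 ± 0.13) and Mcm10 (-0.32 ± 0.07) were among those that fell. The list call was lost at adjusted p = 0.059 with an estimated correlation. Adjusted over the list alone, 14 members fell and 1 rose. Without WT_EV replicate 2, 3 members fell, and Mcm10 lost its call (adjusted p = 0.0759). The number that rose was 0 without WT_EV replicate 1 or 2 or dKO_EV replicate 1. In nucleotide supply 8 of 23 fell, including Dut (-0.35 ± 0.06), Rrm1 (-0.20 ± 0.04) and Rrm2 (-0.17 ± 0.05). The list had 12 adjusted over the list alone and adjusted p = 0.073 with an estimated correlation, and 5 members fell without WT_EV replicate 1. Rrm2 lost its call without WT_EV replicate 2 (adjusted p = 0.247). The haematopoietic stem cell programme rose for 18 of 40 members and fell for 1 (the same numbers adjusted over the list alone), led by Mecom (2.52 ± 0.32) and Cish (1.23 ± 0.09). The list's median was 0.60 over all members but 0.10 over the 22 at a mean of 5 CPM or more, so its rise lay mostly in genes of low count. Its call was lost at adjusted p = 0.059 with an estimated correlation, and 10 members rose without WT_EV replicate 1, while 2 fell without dKO_EV replicate 2. The interferon list fell for 17 of 42 members and rose for 2, at a median of -0.17 (21 and 2 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation). The number that rose was 0 without WT_EV replicate 1 or 2 or dKO_EV replicate 1.

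Markers of other cell types moved as well. Monocyte, macrophage and dendritic markers fell for 17 of 41 members and rose for 8 (19 and 10 adjusted over the list alone), erythroid markers fell for 8 of 24 and rose for 0 (9 and 0), and T and NK cell markers fell for 4 of 14 and rose for 1 (4 and 1). B cell markers fell for 2 of 12 and rose for 0 (3 and 0), while megakaryocyte and platelet markers rose for 6 of 22 and fell for 2 (6 and 2). Camera called these 5 lists, and each call was lost with an estimated correlation (adjusted p = 0.22, 0.059, 0.059, 0.11 and 0.19). The erythroid median was -0.35 over all members but -0.07 over the 12 at a mean of 5 CPM or more. Only 5 T and NK cell members and 4 B cell members reached that level. Without WT_EV replicate 1, 0 T and NK cell members rose. Oxidative phosphorylation fell for 9 of 42 members (9 adjusted over the list alone; 5 and 4 without WT_EV replicate 1 and 2). The unfolded protein response and ATF4 list fell for 12 of 35 and rose for 2 (the same numbers adjusted over the list alone), with 5 lower without WT_EV replicate 1 or 2 and 1 higher without dKO_EV replicate 1. The inflammatory list fell for 5 of 29 and rose for 2 (8 and 2 adjusted over the list alone), with 1 higher without WT_EV replicate 1 or 2, dKO_EV replicate 2 or either dKO_PRMT1 library. Mitosis genes fell for 5 of 47 (0 adjusted over the list alone), which was 0 without WT_EV replicate 1, 2 without WT_EV replicate 2, dKO_EV replicate 2 or dKO_PRMT1 replicate 2, and 3 without dKO_MUT replicate 2. With an estimated correlation the calls of these 4 lists were lost too (adjusted p = 0.31, 0.11, 0.19 and 0.24).

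Rankings of single genes cover called genes at a mean of 5 CPM or more with non-overlapping libraries and an established symbol, here and in the comparisons that follow. Among these, the largest increases outside the Y chromosome were Slc7a2 (2.62 ± 0.19) and Plet1 (2.35 ± 0.26). Apart from Xist, the largest decreases were Itgb2l of the neutrophil list (-3.11 ± 0.16), the cytotoxic protease Gzmb (-2.42 ± 0.09), Hoxa9, Mmp13 (-1.89 ± 0.15) and Cnn3 (-1.85 ± 0.19). The class II invariant chain Cd74 (0.61 ± 0.04) and the MHC class II gene H2-Aa (0.73 ± 0.05) rose, while the lipase Lpl (-0.86 ± 0.04) fell. In all, 1967 genes were called, 1075 higher and 892 lower, 335 of them changed at least 2-fold. Of 29 lists 19 were called, 4 of them with an estimated correlation. The 2 lists named for the pathways of the lost genes were not among them. Wnt and beta-catenin targets rose for 1 of 19 members and fell for 1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.44). The Hox and Meis programme rose for 7 of 29 and fell for 5 (8 and 7 adjusted over the list alone; camera adjusted p = 0.81). The WT_EV libraries expressed Xist at 159 and 121 CPM and had 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty, whereas all 6 dKO libraries had these Y-linked transcripts and 0 counts of Xist. Against a floor of 3 counts in a library, Xist was at least 734-fold lower in dKO_EV and Ddx3y at least 323-fold higher, so genotype and the sex of the source animals cannot be separated here. Counting autosomal genes only, chosen after the data were seen, 1897 genes were called, and without WT_EV replicate 1 or 2 the count over all genes was 1209 or 1149.

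The comparison of dKO_PRMT1 with dKO_EV asks what wild-type PRMT1 changed in dKO cells. Interferon-stimulated genes were lower: 41 of the 42 tested members of the type I interferon list fell (also 41 adjusted over the list alone), at a median of -0.78. The transcription factor Irf7 (-1.36 ± 0.05) and the antiviral genes Rsad2 (-1.87 ± 0.10) and Ifit3 (-1.49 ± 0.08) stood among them, and Lgals3bp (-0.83 ± 0.04) fell as well. Megakaryocyte and platelet markers fell for 14 of 22 members, including Itga2b (-0.85 ± 0.06) and the platelet chemokine Pf4 (-0.92 ± 0.07). Mast cell, basophil and eosinophil markers fell for 9 of 18 and rose for 2, with Cpa3 (-0.69 ± 0.05) and Fcer1a (-1.08 ± 0.09). The stem cell programme fell for 20 of 40 and rose for 2, with Angpt1 (-1.04 ± 0.08), Ly6a (-0.58 ± 0.05) and Gata2 (-0.71 ± 0.06) lower and Gfi1 (0.67 ± 0.07) higher. Adjusted over the list alone the counts were 15 lower for megakaryocytes, 10 lower and 2 higher for mast cells, and 20 lower and 2 higher for the stem cell programme. These 4 lists held with an estimated correlation (adjusted p = 0.0055, 0.021, 0.021 and 0.047). The 2 rising mast cell list members became 1 without dKO_EV replicate 2 or dKO_PRMT1 replicate 1 and 0 without dKO_PRMT1 replicate 2. The 2 rising stem cell members became 1 without dKO_EV replicate 2 or either dKO_PRMT1 library.

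Mitosis genes rose for 20 of 47 members and fell for 0 (30 higher adjusted over the list alone), including the proliferation marker Mki67 (0.37 ± 0.05) and the spindle motor Kif11 (0.23 ± 0.05). That list's call was lost at adjusted p = 0.052 with an estimated correlation. Its count of rising members was 9 without dKO_EV replicate 2, 6 without dKO_PRMT1 replicate 1 and 8 without dKO_PRMT1 replicate 2. DNA replication genes rose for 7 of 58 members and fell for 0, both over all genes and adjusted over the list alone, at a median of 0.11. They included Cdc45 (0.31 ± 0.07), Dna2 (0.28 ± 0.07), Mcm5 (0.16 ± 0.04) and Rfc1 (0.21 ± 0.05) (adjusted p = 0.052 with an estimated correlation). Without either dKO_PRMT1 library 4 members rose. Cdc45 lost its call without dKO_PRMT1 replicate 1 (adjusted p = 0.0618), Rfc1 without dKO_PRMT1 replicate 2 (0.10) and Dna2 without dKO_EV replicate 2 (0.0564). In the list for homologous recombination and the replication checkpoint 7 of 46 rose, among them Topbp1 (0.27 ± 0.05) and Polq (0.54 ± 0.12) (7 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Of these 3 rose without dKO_EV replicate 2, 2 without dKO_PRMT1 replicate 1 and 3 without dKO_PRMT1 replicate 2.

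Neutrophil and granule markers went both ways with wild-type PRMT1, with 15 of 29 higher and 4 lower. The proteases Prtn3 (0.75 ± 0.03) and Elane (0.69 ± 0.03) and myeloperoxidase Mpo (0.56 ± 0.03) rose and Mmp9 (-1.43 ± 0.07) fell (19 and 5 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). The monocyte, macrophage and dendritic list had 15 of 41 members lower and 9 higher, with Lpl (-1.21 ± 0.04), Gpnmb (-0.82 ± 0.03) and the lysosomal protease Ctsb (-0.78 ± 0.03) lower (19 and 10 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). The chemokines Ccl2 (-1.84 ± 0.10) and Ccl4 (-1.88 ± 0.22) fell within the inflammatory list, in which 10 of 29 fell and 0 rose (12 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). T and NK cell markers fell for 6 of 14 and rose for 1 (6 and 1 adjusted over the list alone; adjusted p = 0.061 with an estimated correlation). Among the ranked genes the largest decreases were Ccl5 (-3.07 ± 0.36), Irg1 (-2.41 ± 0.13), Ccl7 (-2.29 ± 0.12), Asprv1 (-2.17 ± 0.26), Gzmb (-2.09 ± 0.12) and Col4a1 (-2.08 ± 0.26). After Prmt1 the largest increases were Myo18b (1.08 ± 0.21), M1ap (1.07 ± 0.26), Ttc21a (1.06 ± 0.21), Bzrap1 (1.05 ± 0.12) and Fcnb (0.97 ± 0.07). In all 1864 genes were called, 759 higher and 1105 lower, 292 of them at least 2-fold. The counts were 1133 without dKO_PRMT1 replicate 1, where M1ap lost its call (adjusted p = 0.0880), and 1058 without replicate 2.

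The comparison of dKO_MUT with dKO_EV gives the same measurement for the enzymatically dead mutant, and interferon genes were lower here as well. Of the 42 tested members 41 fell (41 adjusted over the list alone), at a median of -0.72, with Irf7 (-1.13 ± 0.05), Oasl2 (-0.80 ± 0.05) and Ifit2 (-0.89 ± 0.06) among them. The inflammatory list fell for 11 of 29 members and rose for 0, led by the chemokines Ccl7 (-3.13 ± 0.13) and Ccl2 (-2.61 ± 0.11). Neutrophil and granule markers rose for 17 of 29 members and fell for 0, including Ltf (0.60 ± 0.03), Ngp (0.47 ± 0.03) and Camp (0.52 ± 0.04). Megakaryocyte and platelet markers fell for 12 of 22, including Pf4 (-0.90 ± 0.07) and Thbs1 (-0.66 ± 0.04). These 4 lists held with an estimated correlation (adjusted p = 0.0081, 0.046, 0.021 and 0.021). Adjusted over the list alone the last 3 had 17 lower and 1 higher, 22 higher and 1 lower, and 16 lower and 1 higher. Without dKO_MUT replicate 2, 7 inflammatory members fell. The stem cell programme fell with the mutant too, for 15 of 40 members with 0 higher (18 and 0 adjusted over the list alone), including Ly6a (-0.64 ± 0.05) and Angpt1 (-0.56 ± 0.07). Its call was lost at adjusted p = 0.065 with an estimated correlation. The number that fell was 9 without dKO_MUT replicate 1, and 1 rose without either dKO_EV library.

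Monocyte, macrophage and dendritic markers fell for 21 of 41 members and rose for 6 with the mutant, with Lpl (-1.23 ± 0.04) and Ctsb (-0.80 ± 0.03) lower and F13a1 (0.79 ± 0.04) higher. That list had 22 and 8 adjusted over the list alone, and adjusted p = 0.052 with an estimated correlation, and 3 members rose without dKO_MUT replicate 1. Of the mast cell, basophil and eosinophil markers 5 rose and 2 fell, with Prss34 (0.55 ± 0.08) and Mcpt8 (0.33 ± 0.05) higher and the eosinophil peroxidase Epx (-0.80 ± 0.07) lower. The number that fell was 1 without either dKO_EV or either dKO_PRMT1 library. The list was not called, and its median was 0.04 against a mean of -0.11. DNA replication genes rose for 3 of 58 members, Mcm7 (0.16 ± 0.04), Rfc1 (0.18 ± 0.05) and Cdc45 (0.24 ± 0.07) (1 adjusted over the list alone; adjusted p = 0.065 with an estimated correlation). Without dKO_MUT replicate 2, 1 member rose. Each of the 3 lost its call without at least 1 library: Mcm7 without dKO_EV replicate 2 or dKO_MUT replicate 2 (adjusted p = 0.0653 and 0.288), Rfc1 without dKO_EV replicate 1 or 2 or dKO_MUT replicate 1 (0.0565, 0.0615 and 0.206), and Cdc45 without dKO_EV replicate 1 or either dKO_MUT library (0.0987, 0.115 and 0.107). Cdc45 also missed the threshold in DESeq2 (0.0533). Mitosis genes rose for 4 of 47, including Mki67 (0.31 ± 0.05) (4 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). In the list for homologous recombination and the replication checkpoint 2 of 46 rose and 0 fell (0 adjusted over the list alone; the list was not called), with 1 rising without dKO_EV replicate 2 or dKO_MUT replicate 2 and 0 without dKO_MUT replicate 1. Among the ranked genes the largest decreases beyond Ccl7 and Ccl2 were Mmp13 (-2.43 ± 0.19), Flrt2 (-2.41 ± 0.25), Cd36 (-2.35 ± 0.10) and Irg1 (-2.22 ± 0.13). The largest increases after Prmt1 were Myo18b (1.18 ± 0.21), Serpinf1 (1.08 ± 0.18), the lipid carrier Apoe (1.08 ± 0.11), Glis3 (1.07 ± 0.25) and Mrgpra2b (0.98 ± 0.22). In all 1442 genes were called, 540 higher and 902 lower, 210 of them at least 2-fold, and Mrgpra2b lost its call without dKO_MUT replicate 1 (adjusted p = 0.0573).

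**Figure D2:**
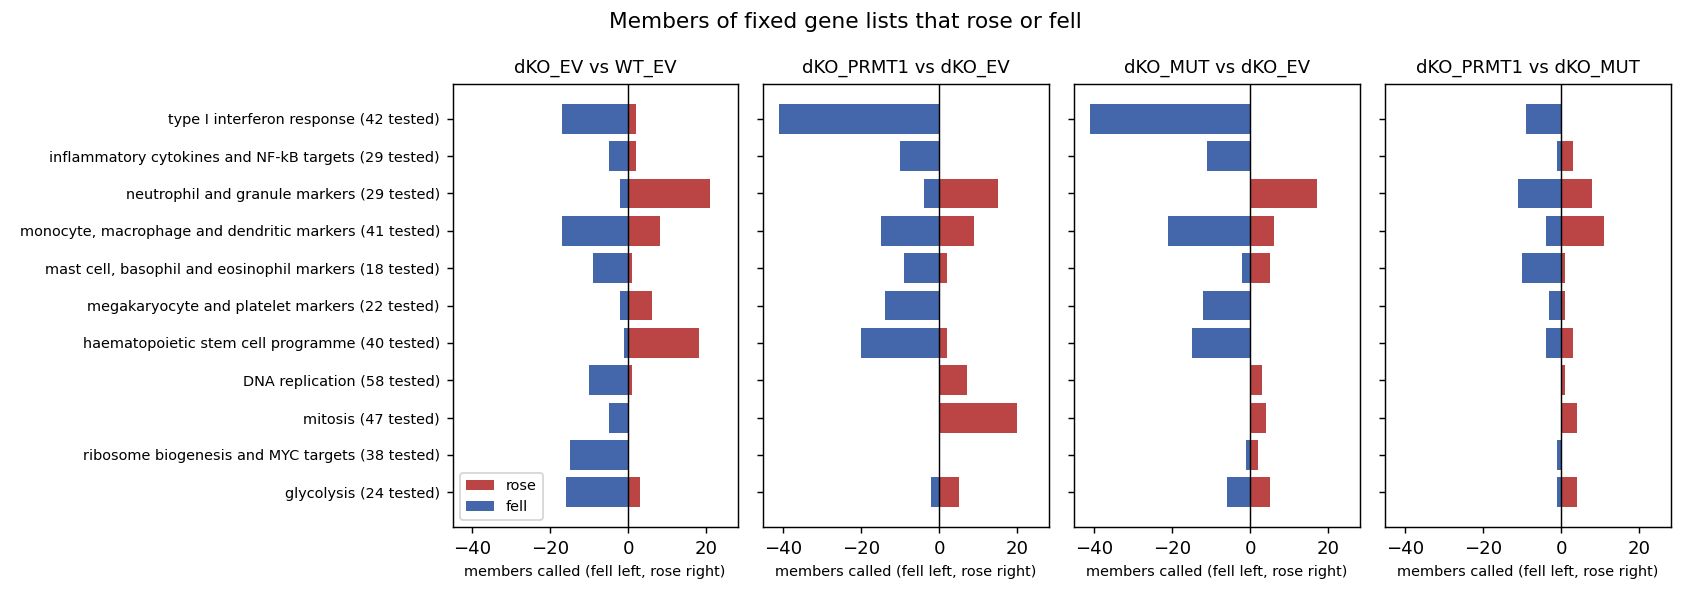
Number of members of 11 gene lists fixed beforehand that rose (right of 0) or fell (left of 0) in each of 4 comparisons, with the number of members tested in parentheses. In both comparisons with dKO_EV, 41 of 42 interferon members fell.

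The direct comparison of dKO_PRMT1 with dKO_MUT sets active against inactive enzyme, with Prmt1 transcript also lower in dKO_PRMT1. Of the mast cell, basophil and eosinophil markers 10 of 18 were lower with the active enzyme and 1 was higher. Those lower included Cpa3 (-0.93 ± 0.05), Prss34 (-1.33 ± 0.08), the IgE receptor chain Fcer1a (-1.36 ± 0.09) and Mcpt8 (-0.87 ± 0.06). The 1 that rose was Epx (0.69 ± 0.07), an eosinophil gene, named after its value was seen. The number higher was 3 without dKO_MUT replicate 1, and 2 without dKO_MUT replicate 2, dKO_PRMT1 replicate 1 or either dKO_EV library. Adjusted over the list alone 10 fell and 4 rose, and this was the 1 list called with an estimated correlation (adjusted p = 0.0058). The neutrophil list went both ways, with 11 of 29 members lower, Retnlg (-1.94 ± 0.10), Mmp9 (-1.47 ± 0.07) and the chemokine receptor Cxcr2 (-1.22 ± 0.09) among them, and 8 higher (13 and 8 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). The mannose receptor Mrc1 (0.82 ± 0.07), the MHC class II gene H2-Ab1 (0.40 ± 0.05) and the class II invariant chain Cd74 (0.33 ± 0.04) were higher. Of the monocyte, macrophage and dendritic list 11 members were higher and 4 lower (14 and 6 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). The number higher was 7 without dKO_MUT replicate 1 and 6 without dKO_PRMT1 replicate 1. The number lower was 0 without dKO_MUT replicate 1 and 1 without any other of the 4 compared libraries. The erythroid list was called lower, at a median of -0.47, with 1 of 24 members higher and 0 lower (2 higher and 8 lower adjusted over the list alone), and 4 fell without either dKO_EV library and 1 without either dKO_MUT library. T and NK cell markers, called lower at a median of -0.47 where the mean was 0.17, had 2 of 14 lower and 1 higher (4 and 3 adjusted over the list alone), with 1 lower without dKO_MUT replicate 1 or dKO_PRMT1 replicate 1 and 0 higher without dKO_MUT replicate 1. Both calls were lost with an estimated correlation (adjusted p = 0.14 and 0.21). Glycolysis genes rose for 4 of 24 and fell for 1 (11 and 2 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). In glycolysis 1 rose without dKO_MUT replicate 1 or either dKO_PRMT1 library, and 2 fell without either dKO_EV library.

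Of the interferon list 9 of 42 members were lower with the active enzyme and 0 higher (17 and 1 adjusted over the list alone), including Rsad2 (-0.78 ± 0.10) and Ifit3 (-0.65 ± 0.08). The list median was -0.13, and the list call was lost at adjusted p = 0.14 with an estimated correlation. The number lower was 4 without dKO_PRMT1 replicate 1 and 5 without dKO_PRMT1 replicate 2. The stem cell programme had 4 of 40 members lower and 3 higher (9 and 3 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with Gata2 (-0.58 ± 0.06) and Angpt1 (-0.48 ± 0.08) lower. The number lower was 2 without dKO_MUT replicate 2 or dKO_PRMT1 replicate 1. Mitosis genes rose for 4 of 47, Hmmr (0.25 ± 0.07), Kif11 (0.19 ± 0.05), Aurka (0.25 ± 0.07) and Prc1 (0.20 ± 0.06) (4 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Of 58 DNA replication genes Dna2 (0.24 ± 0.07) alone rose (0 adjusted over the list alone; the list was not called). Each of these 5 genes lost its call when any of the 4 compared libraries was left out, at adjusted p of 0.0573 to 0.428 for the mitosis genes and 0.175 to 0.300 for Dna2, and Prc1 and Dna2 also in DESeq2 (0.0727 and 0.0602). Without WT_EV replicate 1 or 2, Prc1 (0.0668 and 0.0661) and Dna2 (0.0541 and 0.0543) lost theirs as well. Further large differences were Plet1 (1.31 ± 0.24), Mmp13 (1.12 ± 0.21), Lipg (0.96 ± 0.10), Pald1 (0.85 ± 0.24) and Ccl7 (0.84 ± 0.15) higher, and Gzmb (-1.85 ± 0.12), Ifit1bl2 (-1.47 ± 0.22) and Asprv1 (-1.45 ± 0.26) lower. In all 396 genes were called, 182 higher and 214 lower, 26 of them at least 2-fold. The count was 244 and 240 without dKO_MUT replicate 1 and 2, and 171 and 205 without dKO_PRMT1 replicate 1 and 2; Pald1 lost its call in each of these (adjusted p = 0.155 to 0.373) and in DESeq2 (0.0765), and Mmp13 without dKO_PRMT1 replicate 2 (0.0880).

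The changes with wild-type and dead PRMT1 against dKO_EV were compared next. Among genes called in both, 959 moved the same way, 293 higher and 666 lower, and 14 moved opposite ways. Independent lists of these sizes would share 110.4 and 100.5, which leaves out the shared dKO_EV libraries. Part of the excess over 110.4 may come from those shared controls, since with 2 libraries they were not split. Overlaps exceeded such values in both directions even for dKO_EV vs WT_EV and dKO_PRMT1 vs dKO_MUT, which share no library. There 126 genes moved the same way and 111 opposite ways, against 30.3 and 30.8. The excess over 110.4 alone is therefore no measure of a shared effect. Over the 9938 genes at 5 CPM or more, leaving out Prmt1, Xist and the Y-linked genes, the covariance of the log2 fold changes was 0.0608, against 0.00821 in 20 simulations of unchanged groups sharing the same dKO_EV libraries. The correlation across genes was 0.792 against 0.502. The simulations gave all groups the same spread per gene although replicates differed most in dKO_EV, so the simulated values may be too low. Genes are not independent replicates.

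**Figure D3:**
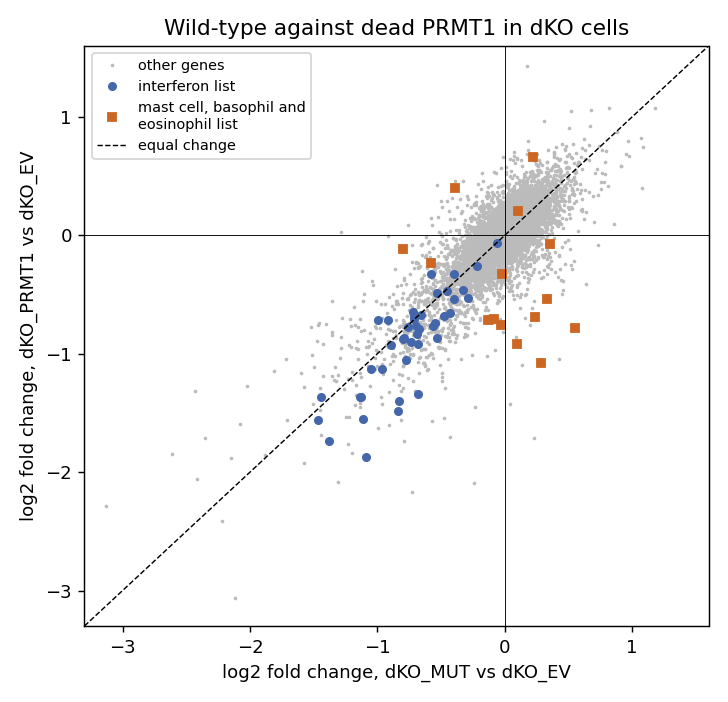
Log2 fold change with wild-type PRMT1 against that with the dead mutant, both relative to dKO_EV, for 9944 genes at a mean of 5 CPM or more (Prmt1 left out). Blue points are the 42 interferon list members and orange squares the 15 members of the mast cell, basophil and eosinophil list at this level; the dashed line marks equal change.

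Whether PRMT1 moved genes against the knockout change was examined with and without shared libraries. Of genes called in both dKO_EV vs WT_EV and dKO_PRMT1 vs dKO_EV, 343 moved opposite ways and 302 the same way. Independent lists would give 146 and 141, which leaves out the shared dKO_EV libraries, so part of the excess of opposite moves may come from them. The covariance of these effects was -0.0117 against -0.00827 in simulations without any change, which share the dKO_EV libraries. The correlation was -0.148 against -0.504. The simulations gave all groups the same spread per gene, but replicates differed most in dKO_EV (chi-square per degree of freedom 6.43, elsewhere 3.65 to 4.55). The simulated covariance may thus be too weak, and its gap from -0.0117 does not show that PRMT1 opposed the knockout change. The count of 343 was 226 and 211 without WT_EV replicate 1 and 2, and 212 and 178 without dKO_PRMT1 replicate 1 and 2. The comparison with no shared libraries, dKO_PRMT1 vs dKO_MUT, holds only the difference between active and dead enzyme. Changes made alike by both inserts cancel in it, so it cannot show whether those opposed the knockout change. The effect of dKO_PRMT1 vs dKO_MUT opposed the knockout effect for 885 of the 1967 genes called in the knockout comparison, or 45.0%. The 95% exact binomial interval was 42.8 to 47.2%. The effects had a Pearson correlation across genes of 0.0651 and a Spearman correlation of 0.0292. Over the 9938 genes at 5 CPM or more, called or not, the correlation was -0.0059, against -0.00067 in the simulations. Genes are not independent, so the interval covers counting error only. Among genes called in both of these comparisons 111 moved opposite ways and 126 the same way, against 30.8 and 30.3 for independent lists.

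The comparison of dKO_PRMT1 with WT_EV asks where the transduced dKO cells stood relative to wild-type cells. Interferon genes were lower for 41 of 42 members (41 adjusted over the list alone), with Irf7 (-1.58 ± 0.05), Rsad2 (-2.39 ± 0.10) and Ifit3 (-1.94 ± 0.08). The inflammatory list fell for 16 of 29 and rose for 2, with Ccl7 (-3.31 ± 0.12) and Ccl2 (-2.67 ± 0.10). Neutrophil markers rose for 23 of 29 and fell for 2, with Camp (1.53 ± 0.04), Cd177 (1.48 ± 0.04) and Ltf (1.18 ± 0.03). Mast cell, basophil and eosinophil markers fell for 12 of 18 and rose for 3, with Prss34 (-2.33 ± 0.08) and Cpa3 (-1.69 ± 0.05). Glycolysis fell for 16 of 24 and rose for 4, with Ldha (-0.87 ± 0.03) and Pgk1 (-0.88 ± 0.04). Erythroid markers fell for 15 of 24 and rose for 1, with Gata1 (-1.60 ± 0.14) and the carbonic anhydrase Car2 (-1.21 ± 0.08). T and NK cell markers fell for 5 of 14 and rose for 1, with Cd28 (-1.47 ± 0.12) and Lat (-1.48 ± 0.15). These 7 lists were called with an estimated correlation (adjusted p = 0.0028, 0.047, 0.0028, 0.0028, 0.035, 0.029 and 0.029). Adjusted over the list alone, the last 6 had 17 lower and 2 higher, 23 higher and 4 lower, 12 lower and 3 higher, 17 lower and 4 higher, 15 lower and 2 higher, and 5 lower and 1 higher. Without any 1 of the 4 WT_EV and dKO_PRMT1 libraries, 1 mast cell, basophil and eosinophil member rose. Without dKO_PRMT1 replicate 1, 1 inflammatory member rose, and without WT_EV replicate 1 or dKO_PRMT1 replicate 2, 0 T and NK cell members rose. Monocyte, macrophage and dendritic markers fell for 19 of 41 and rose for 13 (21 and 13 adjusted over the list alone), megakaryocyte and platelet markers fell for 8 of 22 and rose for 2 (11 and 3), and B cell markers fell for 5 of 12 and rose for 1 (5 and 1). These 3 calls were lost with an estimated correlation (adjusted p = 0.088, 0.071 and 0.071). Without dKO_PRMT1 replicate 1, 1 megakaryocyte member rose, and 0 B cell members rose without WT_EV replicate 1 or 2 or dKO_PRMT1 replicate 2. Ribosome biogenesis and MYC targets fell for 18 of 38 and rose for 0 (24 and 0 adjusted over the list alone), and mitosis genes rose for 9 of 47 and fell for 0 (9 and 0). Their calls were lost as well (adjusted p = 0.0504 and 0.26 with an estimated correlation). The ribosome biogenesis count was 9 and 11 without WT_EV replicate 1 and 2, and 10 and 11 without dKO_PRMT1 replicate 1 and 2. The mitosis count was 5 without WT_EV replicate 1 and 3 without dKO_PRMT1 replicate 1.

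In the same comparison Hoxa9 was at -2.65 ± 0.33 and Ctnnb1 at -0.28 ± 0.04, both called, and Prmt1 at 2.36 ± 0.04. DNA replication genes rose for 6 of 58 and fell for 3 (3 and 2 adjusted over the list alone), with Dna2 (0.51 ± 0.07) and Mcm5 (0.15 ± 0.04) higher and Pcna (-0.18 ± 0.04) lower. Mcm5 lost its call without WT_EV replicate 2 or dKO_PRMT1 replicate 1 (adjusted p = 0.0749 and 0.0567). Without WT_EV replicate 1 or dKO_PRMT1 replicate 2, 3 members rose, and without WT_EV replicate 2 or dKO_PRMT1 replicate 1, 1 rose. Without dKO_PRMT1 replicate 1, 1 member fell. The list was not called, and its median was -0.02 where the test pointed higher. Among the ranked genes the largest decreases apart from Xist were Gzmb (-4.51 ± 0.11), Irg1 (-3.56 ± 0.13), Ccl7 (-3.31 ± 0.12), Mmp13 (-3.20 ± 0.16) and Ccl4 (-2.75 ± 0.21). Outside the Y chromosome Prmt1 and Plet1 (2.38 ± 0.26) increased most. In all 2955 genes were called, 1404 higher and 1551 lower, with 2863 autosomal. Sex was confounded here too, and without dKO_PRMT1 replicate 1 the count was 1954. The matching comparison of dKO_MUT with WT_EV, added after the data were seen, called 2468 genes, 1199 higher and 1269 lower, and 41 of 42 interferon genes fell in it.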

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

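All of the tests of explanations below were chosen after the results they bear on were seen. A set of 14 genes changed in opposite directions with wild-type and with dead PRMT1, both against dKO_EV. Because the genes were selected for called changes of opposite sign, the direct difference between dKO_PRMT1 and dKO_MUT restates that selection and is no further support. As log2 fold changes these differences were -1.36 for Fcer1a, -0.45 for Cd34, -1.05 for Trpm2, -0.87 for Mcpt8, -0.82 for Olfm4, -0.95 for Acvrl1, -1.33 for Prss34, 0.40 for H2-Ab1, 0.33 for Cd74, 0.96 for Lipg, -0.93 for Cpa3, 0.30 for Plxnd1, -0.50 for Mmp8 and 0.40 for Alas1. Independent lists of these sizes would share 100.5 genes in opposite directions.

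Mast cell and basophil markers were lower with wild-type PRMT1 than with the dead mutant. A single aberrant library is argued against, since at least 9 list members fell whichever of the 4 libraries was left out. A smaller share of mast cells and basophils may contribute, as a hypothesis; of the 15 list members at 5 CPM or more 10 fell, but 4 did not pass the threshold and Epx rose (3 rose without dKO_MUT replicate 1, and 2 without dKO_MUT replicate 2, dKO_PRMT1 replicate 1 or either dKO_EV library), and because the list mixes mast cells, basophils and eosinophils this leaves the share of cells and a change within cells open. PRMT1 activity, which the design varies together with the Prmt1 transcript level, also stays open.

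Interferon genes were lower with wild-type and with dead PRMT1 than with the empty vector in dKO cells. An aberrant dKO_EV library is argued against, since at least 39 of 42 members fell in both comparisons whichever dKO_EV library was left out. Fewer monocytes and macrophages stays open as a cause with wild-type PRMT1. There the monocyte list's median lay 0.66 above that of the interferon list, more than the SD of its members (0.485), and 9 rose. The list as a whole thus did not fall with the interferon genes. It mixes monocytes, macrophages and dendritic cells, however, and 15 of its 41 members fell, Lpl, Gpnmb and Ctsb among them. Its median therefore cannot decide whether 1 of these cell types was lost. Fewer monocytes and macrophages also stays open with the dead mutant, where the gap of 0.54 was below the SD (0.573) and 6 rose, fewer without dKO_MUT replicate 1. The gaps and SDs were close, and a wider scatter of the markers raises this bound. These values therefore do not show a difference between wild-type and dead PRMT1. The amount of Prmt1 transcript also stays open: the mutant had more of it by count, while 9 members were lower with wild-type PRMT1 and 0 higher, but 4 were lower without dKO_PRMT1 replicate 1 and 5 without replicate 2, and the share of the insert's transcript counted at mouse Prmt1 is unknown. A circumstance of the empty-vector cultures other than the insert cannot be told apart from an effect of PRMT1 protein independent of its activity, since no dKO library had another insert; the list's median in dKO_EV against WT_EV was -0.17.

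The calls between dKO_EV and WT_EV coincide with a difference in sex-linked transcripts. Direct dosage of X- and Y-linked genes covers only genes on those chromosomes, and 96.4% of the called genes were autosomal. In dKO_PRMT1 vs dKO_EV, where all libraries had Y-linked transcripts, 1816 of 1864 called genes were autosomal as well. The share therefore gives no test of an effect of sex. The sex of the source animals acting on autosomal genes cannot be told apart from the genotype, because 0 of the 6 dKO libraries lacked Y-linked transcripts. The knockout itself stays open as the biological explanation, as do other differences between the animals.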

How the results depend on the processing

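The autosomal counts and the list-member counts below were chosen after the data were seen. With a threshold of 0.01 the calls were 1209 (dKO_EV vs WT_EV), 1139 (dKO_PRMT1 vs dKO_EV), 897 (dKO_MUT vs dKO_EV) and 219 (dKO_PRMT1 vs dKO_MUT), as a stricter threshold must lower them. Leaving out 1 library gave 1149 to 1996, 1058 to 1945, 171 to 550 (dKO_PRMT1 vs dKO_MUT) and 1954 to 3394 (dKO_PRMT1 vs WT_EV) calls; a group of 1 library is assumed to vary like the others and the cause was otherwise not tested. With an estimated correlation the lists called were 4, 4, 4, 1 and 7 in the order of the report. Without single libraries the unshared opposition was 43.1 to 48.0% and the shared count 178 to 413. For gene calls, the other alternatives named in the methods and the autosomal counts (1897 and 2863) stayed within 1.5 times. For the lists and both oppositions, only DESeq2 size factors, the 5 CPM filter and the replicate block were run, also within 1.5 times. Fits of the compared groups alone gave 1685, 1672, 1164, 508 and 3751 calls against 1967, 1864, 1442, 396 and 2955, in the order of the report. These were fewer in each comparison with dKO_EV, whose replicates differed most, and more elsewhere. With 1 spread for all groups, comparisons with dKO_EV may call too many genes. Replicate numbers are not known to pair samples (correlations of deviations -0.0502 to 0.000489), and a replicate block gave 1952, 1853, 1414, 403 and 2953 calls. Values that changed sign were of effects not called with all 8 libraries: over the left-out libraries Prmt1 in dKO_EV vs WT_EV ran from -0.0095 to 0.0293, Hoxa9 in dKO_MUT vs dKO_EV from -1.24 (past the threshold, without dKO_MUT replicate 1) to 0.0686, and Hoxa9 in dKO_PRMT1 vs dKO_MUT from -0.881 to 0.526. Depth limits genes as low as Hoxa9, with 36 to 104 counts in the libraries with an insert.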

Other observations

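The principal component analysis, the Rn45s share and the counts without single libraries were chosen after the data were seen. Erythroid markers fell in dKO cells with wild-type PRMT1 against dKO_EV, with 11 of 24 members lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), among them Car2 (-0.93 ± 0.08), Gfi1b (-1.29 ± 0.15) and Gata1 (-0.95 ± 0.14). Without dKO_PRMT1 replicate 1, 6 erythroid members fell, and 1 rose without dKO_EV replicate 2 or dKO_PRMT1 replicate 1. With the dead mutant 6 fell and 0 rose without a list call (8 and 2 adjusted over the list alone), and 2 fell without dKO_MUT replicate 2, while 1 rose without dKO_EV replicate 2. Immediate early genes rose for 11 of 27 members and fell for 1 in dKO_EV against WT_EV, with Fos (0.66 ± 0.08) and Egr1 (0.87 ± 0.12) (12 and 2 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), and 2 fell without dKO_EV replicate 2 or either dKO_MUT library. They fell for 10 and rose for 2 with wild-type PRMT1 against dKO_EV, with Jund (-0.63 ± 0.06) and Atf3 (-0.79 ± 0.09) (11 and 3 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), and 6 fell without dKO_PRMT1 replicate 2. The number that rose was 1 without dKO_EV replicate 2 or dKO_PRMT1 replicate 2 and 0 without dKO_PRMT1 replicate 1. With the dead mutant they fell for 9 and rose for 1, with Jund (-0.74 ± 0.06) and Atf3 (-1.01 ± 0.09) (11 and 2 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Heat shock proteins fell for 6 of 17 in dKO_EV against WT_EV, with Hsp90aa1 (-0.29 ± 0.03) and Hspd1 (-0.29 ± 0.04) (7 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). The p53 targets rose for 7 of 34 and fell for 3 there, without a list call, and fell for 7 and rose for 1 with wild-type PRMT1, with Tap1 (-0.61 ± 0.05) and Plk2 (-1.11 ± 0.20) (12 and 1 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Of the p53 targets in dKO_EV against WT_EV, 4 rose without WT_EV replicate 1, and 1 fell without WT_EV replicate 1 or 2. With wild-type PRMT1, 3 fell without dKO_PRMT1 replicate 1 and 4 without replicate 2, and 2 rose without dKO_EV replicate 2. With the dead mutant 5 p53 targets fell and 2 rose without a list call (the same numbers adjusted over the list alone). There 3 fell without any 1 of the WT_EV, dKO_MUT and dKO_PRMT1 libraries, and 1 rose without dKO_EV replicate 1 or either dKO_MUT library. In dKO_PRMT1 against dKO_MUT 2 of 34 fell and 0 rose (4 and 1 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). There 4 fell without either dKO_EV library, 1 without either WT_EV library, dKO_MUT replicate 1 or dKO_PRMT1 replicate 2, and 0 without dKO_MUT replicate 2 or dKO_PRMT1 replicate 1. The Fanconi anaemia list was not called in any comparison.

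In a principal component analysis of 6102 genes the first component, 61.9% of the variance, ordered the libraries from WT_EV (-13.3 and -13.9) through dKO_EV (-3.46 and -4.07) to dKO_MUT (8.28 and 7.93) and dKO_PRMT1 (9.22 and 9.25). The second, 15.2%, set dKO_EV (-8.05 and -7.47) apart from the other groups, and the third, 9.26%, separated dKO_MUT (4.98 and 5.65) from dKO_PRMT1 (-5.06 and -4.55). The ribosomal RNA gene Rn45s took 0.308 to 0.498% of the counts of a library, with both WT_EV libraries at the top of that range (0.471 and 0.498%). Prmt2 stood at 5.66 and 6.18 CPM in dKO_EV, 3.45 and 3.96 CPM in dKO_MUT and 3.36 and 3.14 CPM in dKO_PRMT1. Its level was thus similar with both inserts, although it was not called with the dead mutant. Prmt2 fell (log2 fold change -0.87 ± 0.28) with wild-type PRMT1 against dKO_EV (adjusted p = 0.029, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 89 and 138 counts to 67 and 62. That call was lost in DESeq2 and without WT_EV replicate 1 or 2, dKO_EV replicate 2, or dKO_PRMT1 replicate 1 or 2, at adjusted p of 0.0514 to 0.183.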
